A study of Rattus norvegicus with 8 samples.

How the data were processed

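Liver RNA of 8 rats was profiled by RNA-seq, 3 on normal chow (ND) and 5 on a high fat diet (HFD), with a TruSeq RNA library kit, per the labels' protocols. The groups and replicate numbers come from the sample titles. The labels give the age as about 22 weeks and the diet as 24 weeks, and this difference was not resolved. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.2.1 and Cuffdiff were used with the genome build Rnor_6.0; which tool made which column, the annotation release and the use of strand are not given in the sources used here. The authors deposited whole-number counts and FPKM per Ensembl gene for each sample, and the gene FPKM equal the count divided by gene length and table total (largest relative difference of the implied lengths 1.7e-05). For lncRNAs the authors deposited FPKM and a signal per transcript. The signal is an estimated number of fragments times 1 constant per sample: of values up to 20 fragments, 83.4% to 84.5% per library were whole multiples of that constant within 0.02 fragments. The 4 columns of group values in the lncRNA table are the means of the libraries of each diet (largest relative difference 0.0042) and were not used.

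The design, written before the data were examined, assumed FPKM for genes and named edgeR in case counts were found. Counts were found, so genes were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, 2-sided) in R 4.3.3, and 14148 of 32545 genes were kept. FPKM are given as levels and log2 fold changes come from the edgeR fit. The lncRNAs were tested with limma 3.58.1 with a variance trend on log2(FPKM + 0.5), for transcripts with FPKM of at least 0.5 in at least 3 samples; these differences understate the change of low transcripts. Benjamini-Hochberg adjusted p under 0.05 counted as passing. Gene lists, 26 in all with 570 of 587 symbols found in the table by symbol or by a synonym in a RefSeq gene table of assembly GRCr8, were fixed beforehand. Those with at least 5 tested members were tested by camera with a preset correlation of 0.01, and beside it with an estimated correlation and by fry. A list score is the mean of centred log2 CPM over the tested members, where CPM are edgeR's counts scaled by library size. For Lnc19959.2, Purb and Hnrnpa2b1, log2 means were compared by an exact permutation test over 56 arrangements, 2-sided.

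Named genes followed a fixed rule: the 10 largest rises and falls among passing genes with a symbol, mean FPKM of at least 1 and ranges that do not overlap, or, with under 5 such genes in a direction, the 5 with the smallest p; for each list, the 2 members with the smallest p and up to 2 others that pass; and Purb, Hnrnpa2b1, Apoa4, Cpt1a, Gpam and Tm7sf2. lncRNAs followed the same rule with 5 per direction. Genes named outside this rule were chosen after their values were seen: Pnpla3, Scd1, Fasn, Srebf1, Bhmt, Cps1, Slc35c2, Elmo2, Pnpla5, LOC100909412, Ppap2b, Acsl5, Cdh22 and the named clock genes other than Arntl and Cry1. Also looked at after the fact, and given only where a value changes, were Ppara, Acaca, Alb, Cyp7a1, Mlxipl, Kdm5d, Eif2s3y and Cyp2c11.

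On simulated counts with the real library sizes and 13991 genes, the gene test recovered 52% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, with 5 false calls among 153. The lncRNA test, run on 19799 transcripts, recovered 50% of 100 transcripts with a log2 change of 2 and 83% of 100 with a log2 change of 4. The changed genes were drawn only from genes above a set level. Genes and transcripts were simulated independently of each other and without depth sets, so recovery in the real data may be lower. Planting many changed genes also makes the adjusted threshold easier to pass: 153 genes were called there and 1 in the real data. The shares recovered therefore do not give the power of the real comparison. The lowest chi-square per degree of freedom between libraries of a diet was 23.9, more than sampling noise gives. The biological coefficient of variation between libraries was 26%. Each rat gave 1 library, and the p-values of the gene, lncRNA and permutation tests measure the spread between these rats. Those of camera with the preset correlation compare the genes of a list with other genes at an assumed correlation, and do not measure that spread. Alternatives were other filters, scalings, pseudocounts and variance models, DESeq2 1.42.0, sample weights, a block for the replicate number and leaving out each library, and, chosen after seeing the data, the depth set as a covariate (parted between 18401981 and 30501673 counts), limma on log2(FPKM + 1) for genes and edgeR on lncRNA fragments rescaled and rounded to whole numbers.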

Results

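RNA from the livers of Sprague-Dawley rats, an outbred laboratory strain, was sequenced to find transcripts, long noncoding RNAs (lncRNAs) among them, that differ between a normal chow diet (ND) and a high fat diet (HFD). Libraries came from 3 ND rats and 5 HFD rats, out of 12 rats per diet. The labels give fat as 8.5% for the chow and 41% for the high fat diet, and the feeding time as 24 weeks, which is longer than the age they give. The deposited gene counts summed to between 12678616 and 36152937 per library. The libraries fell into 2 depth sets. ND-1, ND-3, HFD-1 and HFD-2 held 30501673 to 36152937 counts, and ND-2, HFD-3, HFD-4 and HFD-5 held 12678616 to 18401981. The sets also differed in the share of counts on small nucleolar RNA genes, which was 0.0667% to 0.0979% in the deep set and 0.111% to 0.141% in the shallow set. Of 20 tested genes of the circadian clock list, 15 lay outside the range of the other 7 libraries in ND-3, 7 above and 8 below, and at most 7 in any other library. Arntl, which encodes the clock activator BMAL1, was at 13.5 FPKM in ND-3 against 0.384 to 1.57 FPKM, and Dbp, a clock-controlled transcription factor gene, at 1.55 FPKM against 15.9 to 36.5 FPKM.

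The first comparison asked which genes differ in the liver between the diets. Fer1l5, a member of the ferlin family (ENSRNOG00000024201, Rnor_6.0 chromosome 9, 42945358 to 42998109), fell from 1.27 ± 0.133 FPKM (SD, n = 3) on chow to 0.386 ± 0.0529 FPKM (SD, n = 5) on the high fat diet. Its log2 fold change was -1.74 ± 0.17 (SE), with an adjusted p of 0.0272 by edgeR's quasi-likelihood test, and all 5 HFD libraries lay below the 3 ND libraries. It was the 1 gene of 14148 tested that passed. The 5 genes with the smallest p among those higher on the high fat diet did not pass. Of these, 4 are given here: Aldh1a1, a retinaldehyde dehydrogenase (26.5 ± 6.79 against 151 ± 47.2 FPKM, adjusted p = 0.0579), Vnn1, a pantetheinase (2.28 ± 0.396 against 10.8 ± 3.42 FPKM, adjusted p = 0.0625), and Nr1i3 and Ech1 (both adjusted p = 0.0851). Among genes that were lower, G6pdx, which encodes glucose-6-phosphate dehydrogenase, went from 12.4 ± 5.66 to 3.13 ± 0.737 FPKM (adjusted p = 0.0689). The interleukin-25 receptor gene Il17rb went from 5.0 ± 1.23 to 1.83 ± 0.313 FPKM (adjusted p = 0.0689), and Acss2 and Ebp had adjusted p of 0.0732 and 0.0851. At an unadjusted p under 0.05 there were 808 genes, 407 higher and 401 lower, where 707 are expected by chance. DESeq2, an alternative chosen before the data were examined, called 131 genes, 63 higher and 68 lower. With the depth set as a covariate, an alternative chosen after seeing the data, edgeR called 5 genes: Fer1l5, G6pdx, Acss2 and Pnpla5 lower, and LOC100909412 (ENSRNOG00000050499) higher. Fer1l5 did not pass without ND-2, ND-3, HFD-1, HFD-2 or HFD-4, where its adjusted p reached 0.0997.

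Genes of lipid synthesis were lower on the high fat diet as groups. Of 25 tested genes of cholesterol synthesis and uptake, all 25 had lower fitted values, with a median log2 fold change of -1.30, and 21 passed adjusted over the list alone (0 over all genes). Ebp and Lss, enzymes of the late steps of the pathway, went from 82.1 ± 17.4 to 43.6 ± 4.24 FPKM and from 14.8 ± 4.74 to 5.72 ± 1.254 FPKM (SD, n = 3 and n = 5; both p adjusted over the list alone = 0.00111). Tm7sf2, a sterol reductase, was at 31.8 ± 13.2 FPKM on chow and 9.87 ± 9.17 FPKM on the high fat diet (p adjusted over the list alone = 0.0208), with HFD-3 at 26.1 FPKM and the other HFD libraries between 3.51 and 7.27 FPKM. Of 30 tested genes of fatty acid and triglyceride synthesis, 26 had lower fitted values, with a median log2 fold change of -1.01, and 18 passed adjusted over the list alone, each of them lower (0 over all genes). Without ND-2 the median was -0.638 and 12 passed. Acss2, which makes acetyl-CoA from acetate, went from 51.9 ± 22.0 to 15.1 ± 2.79 FPKM, and Gpam, which acylates glycerol-3-phosphate, from 76.7 ± 45.8 to 19.6 ± 7.03 FPKM (p adjusted over the list alone = 0.000541 and 0.00287). Chosen after its values were seen, Fasn, which encodes fatty acid synthase, went from 326 ± 234 to 35.1 ± 22.6 FPKM (log2 fold change -3.20, adjusted p = 0.132), and its log2 fold change was -2.50 without ND-2.

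Both synthesis lists passed camera with its preset correlation of 0.01 and with an estimated correlation (adjusted p = 0.0227 for each). The difference of the mean list score between the diets was the most extreme of the 56 arrangements for either list (exact permutation p = 0.0179, 2-sided, the smallest that 3 against 5 samples allow). This p was computed for all 26 lists and not adjusted over them, and it was the same for fatty acid oxidation and xenobiotic metabolism. The score differences were -1.15 in the deep set and -1.57 in the shallow set for cholesterol synthesis, and -1.12 and -1.67 for fatty acid and triglyceride synthesis. The shallow values rest on ND-2, the only ND library of that set. Its scores, 1.17 for cholesterol synthesis and 1.27 for fatty acid and triglyceride synthesis, were the highest of all libraries. With an estimated correlation the fatty acid list did not pass without ND-2 (adjusted p = 0.0890), HFD-1 (0.0591) or HFD-2 (0.0615), and the cholesterol list without those 3 libraries, at the same values, or without ND-3 (0.0548).

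**Figure D1:**
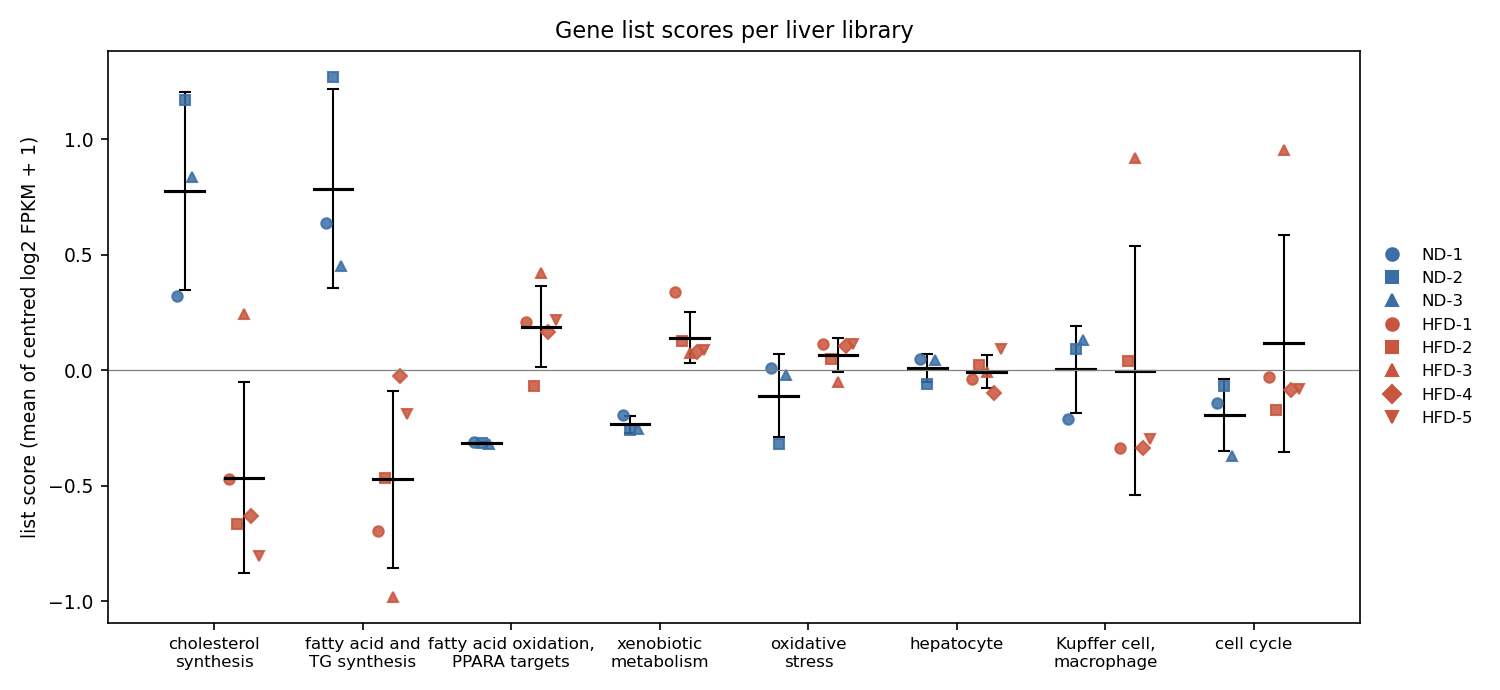
Scores of 8 gene lists in the 8 liver libraries (blue ND, red HFD). The y axis is the mean of the members' log2 CPM (edgeR's counts scaled by library size), centred on the mean of all libraries. The axis label names log2 FPKM + 1 in error. Lines and bars are means ± SD (n = 3 and n = 5). All ND libraries lie above all HFD libraries for both synthesis lists and below them for fatty acid oxidation and xenobiotic metabolism, and HFD-3 lies at 0.92 for the Kupffer cell and 0.951 for the cell cycle list.

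Genes of fatty acid oxidation, ketogenesis and PPARA targets were higher on the high fat diet as a group: 34 of 37 tested genes had higher fitted values, with a median log2 fold change of 0.41, and 6 passed adjusted over the list alone (0 over all genes). That count was 17 without HFD-2, 10 without ND-1 and 4 to 7 without any other library. Vnn1 and Ech1, the latter a dienoyl-CoA isomerase, led the list (p adjusted over the list alone = 0.000490 and 0.00135), and Ech1 stood at 41.5 ± 2.75 FPKM on chow and 106 ± 26.2 FPKM on the high fat diet. Cpt1a, which admits long-chain fatty acids to the mitochondrion, was at 36.7 ± 20.4 and 74.9 ± 21.1 FPKM and did not pass (p adjusted over the list alone = 0.0630). Genes of xenobiotic metabolism were also higher: 24 of 33 had higher fitted values, with a median log2 fold change of 0.30, and 7 passed adjusted over the list alone (0 over all genes). Aldh1a1 and Nr1i3, the gene of the constitutive androstane receptor, had the smallest p (0.000270 and 0.000913 adjusted over the list alone), and Nr1i3 was at 17.9 ± 3.63 and 50.9 ± 10.6 FPKM. Reads of near-identical cytochrome P450 genes cannot be assigned with certainty, so the levels of single members of that family are uncertain. In the oxidative stress list 15 of 24 genes had higher fitted values and 2 passed adjusted over the list alone, namely Akr7a3, an aldo-keto reductase (38.5 ± 12.7 against 146 ± 48.7 FPKM, p adjusted over the list alone = 0.0032), and Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis (79.1 ± 12.4 against 172 ± 56.4 FPKM, p adjusted over the list alone = 0.0176). The score differences in the deep and the shallow set were 0.383 and 0.583 for fatty acid oxidation, 0.455 and 0.338 for xenobiotic metabolism and 0.0867 and 0.374 for oxidative stress. The shallow values rest on ND-2, the only ND library of that set. Without ND-1, ND-2 or ND-3, 1 gene of the oxidative stress list passed adjusted over the list alone. With an estimated correlation these lists had adjusted p of 0.0315 for fatty acid oxidation, 0.0227 for xenobiotic metabolism and 0.0497 for oxidative stress. The first was at 0.0852 and the last at 0.0702 with the depth set as a covariate. Leaving out 1 library took the adjusted p to as much as 0.131 for fatty acid oxidation (not passing without ND-1, ND-2, ND-3, HFD-1 or HFD-5), 0.0890 for xenobiotic metabolism (without ND-2, ND-3 or HFD-2) and 0.251 for oxidative stress (in 7 of 8 cases, all but HFD-5).

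**Figure D2:**
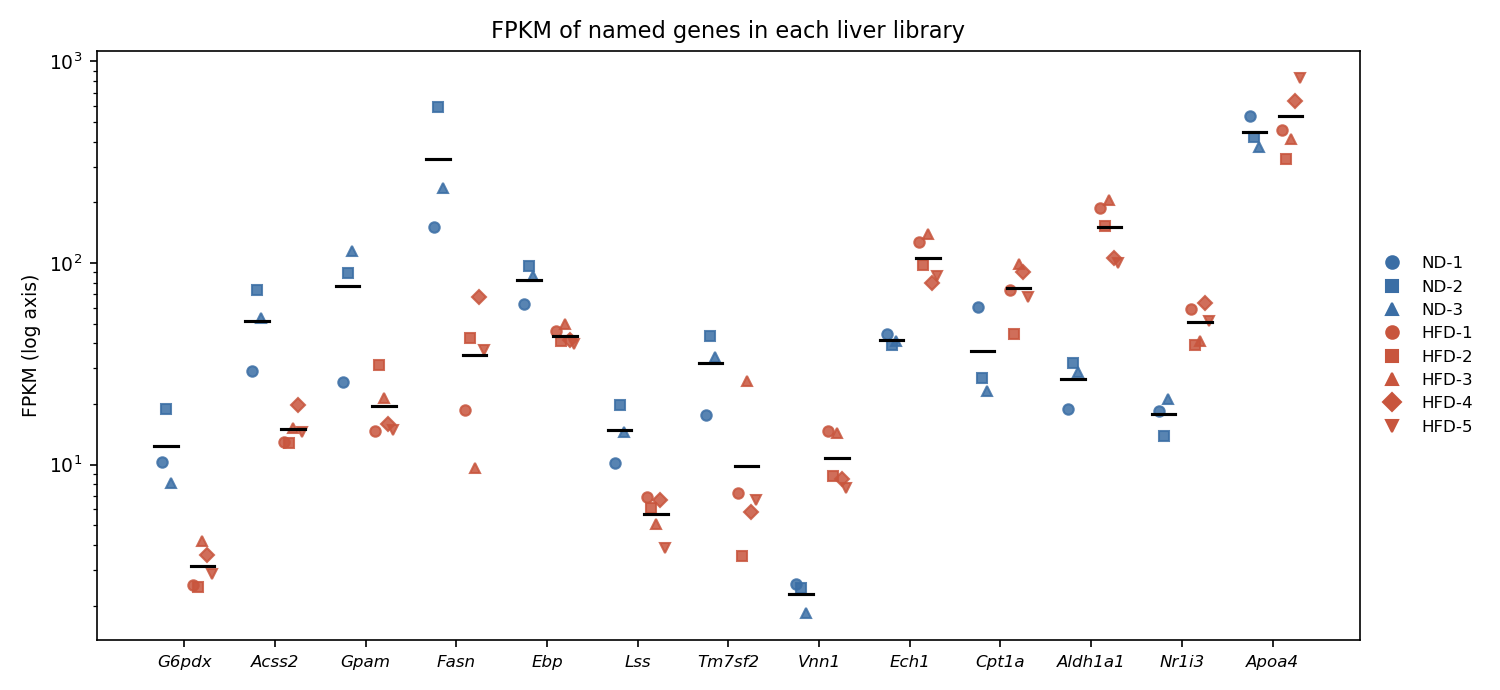
FPKM of 13 named genes in each library (y axis, log scale; blue ND, n = 3; red HFD, n = 5; black lines are group means). The HFD libraries lie below the ND libraries for G6pdx, Acss2, Fasn, Ebp and Lss and above them for Vnn1, Ech1, Aldh1a1 and Nr1i3, and the diets overlap for Gpam, Tm7sf2, Cpt1a and Apoa4.

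Another 4 lists passed camera only with the preset correlation. Of 36 genes of amino acid metabolism and the urea cycle, 31 had lower fitted values and 0 passed adjusted over the list alone, with an adjusted p of 0.339 with an estimated correlation. Without HFD-5, 8 passed lower and 1 higher adjusted over the list alone, and without ND-2, 1 passed lower. Its score difference was -0.822 in the deep set and 0.106 in the shallow set. ND-2 is the only ND library of the shallow set, here and for the lists below. Whether the direction differs between the sets therefore cannot be told from the level of that rat. Oat, ornithine aminotransferase, was at 166 ± 53.2 and 79.6 ± 16.4 FPKM, while Glul, glutamine synthetase, was at 135 ± 25.5 and 241 ± 60.8 FPKM. Of 23 genes of bile acid and sterol disposal, 18 had higher fitted values and 0 passed adjusted over the list alone. The list had an adjusted p of 0.138 with an estimated correlation. Nr0b2, the gene of the receptor SHP, was among the 18, at 16.5 ± 3.74 and 46.5 ± 22.2 FPKM. The score differences of this list were 0.0243 in the deep set and 0.587 in the shallow set, and it did not pass without ND-2 (adjusted p = 0.151). The cell cycle list (22 genes, 18 with higher fitted values) and the list of sex-linked and sex-dependent genes (9 genes, 8 lower) had adjusted p of 0.924 and 0.487 with an estimated correlation. In each of these lists 0 genes passed adjusted over the list alone. In the deep and the shallow set their score differences were 0.158 and 0.33 for cell cycle and -0.145 and -0.491 for sex-linked genes. The cell cycle score of HFD-3 was 0.951 and those of the other HFD libraries lay between -0.171 and -0.0278, and the list did not pass without HFD-3 (adjusted p = 0.883) or ND-3 (0.297). Of the sex-dependent genes Cyp2c12, a steroid hydroxylase, was at 78.5 ± 46.9 and 35.1 ± 18.5 FPKM, and that list did not pass without ND-1 (adjusted p = 0.122) or HFD-3 (0.0827). In all, camera with the preset correlation called 9 of 24 lists, and other arrangements of the 8 libraries gave a median of 9.

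The other 15 lists did not pass, with a smallest adjusted p of 0.0543 for the endothelial cell markers. They covered lipid droplets and lipolysis, lipoproteins and fatty acid uptake, glucose metabolism, acute phase and inflammation, the unfolded protein response, the circadian clock, oxidative phosphorylation and immediate early genes, and markers of hepatocytes, Kupffer cells and macrophages, lymphocytes and neutrophils, stellate cells, endothelial cells, cholangiocytes and erythroid cells. In 9 of them the median, the mean and the direction of the test differed in sign. Apoa4, which encodes a lipoprotein of chylomicrons, was at 444 ± 82.6 FPKM on chow and 533 ± 202 FPKM on the high fat diet (adjusted p = 0.993). Lbp, the lipopolysaccharide binding protein gene, was the acute phase gene that passed by edgeR (10.3 ± 0.849 against 22.1 ± 5.57 FPKM, p adjusted over the list alone = 0.0102), and it did not pass without ND-1 or without ND-3. HFD-3 had scores of 0.92 for Kupffer cells, 0.93 for lymphocytes and neutrophils and 0.928 for the acute phase, each the highest of the 8 libraries. Without HFD-3 the Kupffer cell and acute phase lists passed camera with the preset correlation in the lower direction (adjusted p = 0.000474 and 0.0311), but not with an estimated correlation (adjusted p = 0.447 and 0.463), and without ND-3 the erythroid list passed in the higher direction (2.05e-12, and 0.0548 with an estimated correlation). The markers of pancreas and adipocytes had 2 and 4 tested members, under the minimum of 5, and were not tested as lists. Car3, carbonic anhydrase 3, passed by edgeR over the adipocyte list (p adjusted over the list alone = 0.0073) at 1563 ± 210 and 2521 ± 421 FPKM, and is also made by hepatocytes.

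The second comparison asked which lncRNAs differ between the diets, the stated purpose of the series. Of 31243 transcripts, 19799 were tested and 2 passed limma's test. NONRATT001594.2 (681 nt, chromosome 1, 238212160 to 238244014) rose from 143 ± 25.6 to 837 ± 222 FPKM, a log2 difference of 2.52 ± 0.23 (SE, adjusted p = 0.00705), and it overlaps Aldh1a1, whose own log2 fold change was 2.50. TCONS_00183685 (2460 nt, chromosome 5, 124696657 to 124699196) fell from 20.9 ± 3.72 to 0.0282 ± 0.0280 FPKM (log2 difference -5.33, adjusted p = 0.00358). It lies in the span of Ppap2b, whose log2 fold change was 0.14. A second transcript with the same start and end, TCONS_00183684, 2468 nt long, was at 58.2 to 139 FPKM on chow and 59.3 to 132 FPKM on the high fat diet. TCONS_00183685 made up 14.5% to 23.8% of the sum of both on chow and 0.0178% to 0.0591% on the high fat diet. That sum overlapped between the diets, at 74.8 to 162 FPKM on chow and 59.4 to 132 FPKM on the high fat diet. How reads common to both transcripts were divided between them is not given in the sources used here. The next transcripts in order of p did not pass. NONRATT000562.2 (150 ± 16.1 against 426 ± 119 FPKM, adjusted p = 0.199) overlaps Ech1, and NONRATT001874.2 (439 ± 67.4 against 219 ± 19.1 FPKM, adjusted p = 0.164) and NONRATT001876.2 (adjusted p = 0.199) overlap Acsl5. TCONS_00204310, NONRATT003647.2 and NONRATT008053.2 were at or near 0 FPKM in the ND libraries, with means of 5.62 ± 2.01, 9.10 ± 6.43 and 5.75 ± 2.78 FPKM on the high fat diet (adjusted p = 0.113, 0.199 and 0.199). NONRATT018370.2 and NONRATT012966.2 were at 8.80 ± 4.07 and 12.1 ± 9.24 FPKM on chow and 0.332 ± 0.498 and 0.304 ± 0.679 FPKM on the high fat diet (both adjusted p = 0.269). At an unadjusted p under 0.05 there were 1031 transcripts, with 990 expected by chance. Of the tested transcripts 80.2% overlap the span of a gene, and the use of strand in the counting is not given in the sources used here, so reads of a lncRNA and of an overlapping gene cannot be told apart. NONRATT001594.2 did not pass without ND-1 or ND-3 (adjusted p up to 0.12), and TCONS_00183685 could not be tested without any 1 ND library.

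The third comparison concerned the lncRNA and the proteins that the series title names. Lnc19959.2 was taken to be NONRATT019959.2 from the number in its identifier (717 nt, chromosome 3, 161802043 to 161803463). It was at 37.7 ± 36.1 FPKM (SD, n = 3) on chow and 124 ± 54.0 FPKM (SD, n = 5) on the high fat diet. The log2 difference of 2.10 did not pass the exact permutation test (p = 0.0536, 2-sided; 0.161 adjusted over the 3 items), and limma's adjusted p over all lncRNAs was 0.805. Without ND-2 the difference was 1.20 (exact permutation p = 0.19), and the unadjusted exact permutation p was 0.0476 without ND-3 and 0.0286 without HFD-4. It was higher than every ND library in 4 of 5 HFD libraries, with HFD-4 at 34.9 FPKM and ND-3 at 77.4 FPKM. The log2 difference was 1.45 in the deep set and 3.74 in the shallow set, which holds 1 ND library. The transcript lies inside the span of Slc35c2 (ENSRNOG00000018649, chromosome 3, 161801197 to 161812291), a solute carrier gene that was at 10.7 ± 10.1 and 37.3 ± 18.3 FPKM (exact permutation p = 0.107). It also lies in the span of Cdh22, which was listed at 0 FPKM in every library. Over the 8 libraries log2 Lnc19959.2 and log2 Slc35c2 had a Pearson r of 0.983 (exact permutation p = 0.000174) and a Spearman rho of 0.976 (exact permutation p = 0.000397), the 1 pair of a lncRNA and a gene tested singly. Without ND-2 and HFD-4, the libraries farthest from the median, r was 0.9999. Within the deep and the shallow set, of 4 libraries each, samples were too few for a correlation. Purb, which encodes a purine-rich element binding protein, was at 8.05 ± 0.324 and 9.15 ± 0.956 FPKM (exact permutation p = 0.125), and Hnrnpa2b1, an RNA binding protein gene, at 147 ± 18.4 and 135 ± 20.3 FPKM (exact permutation p = 0.286).

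**Figure D3:**
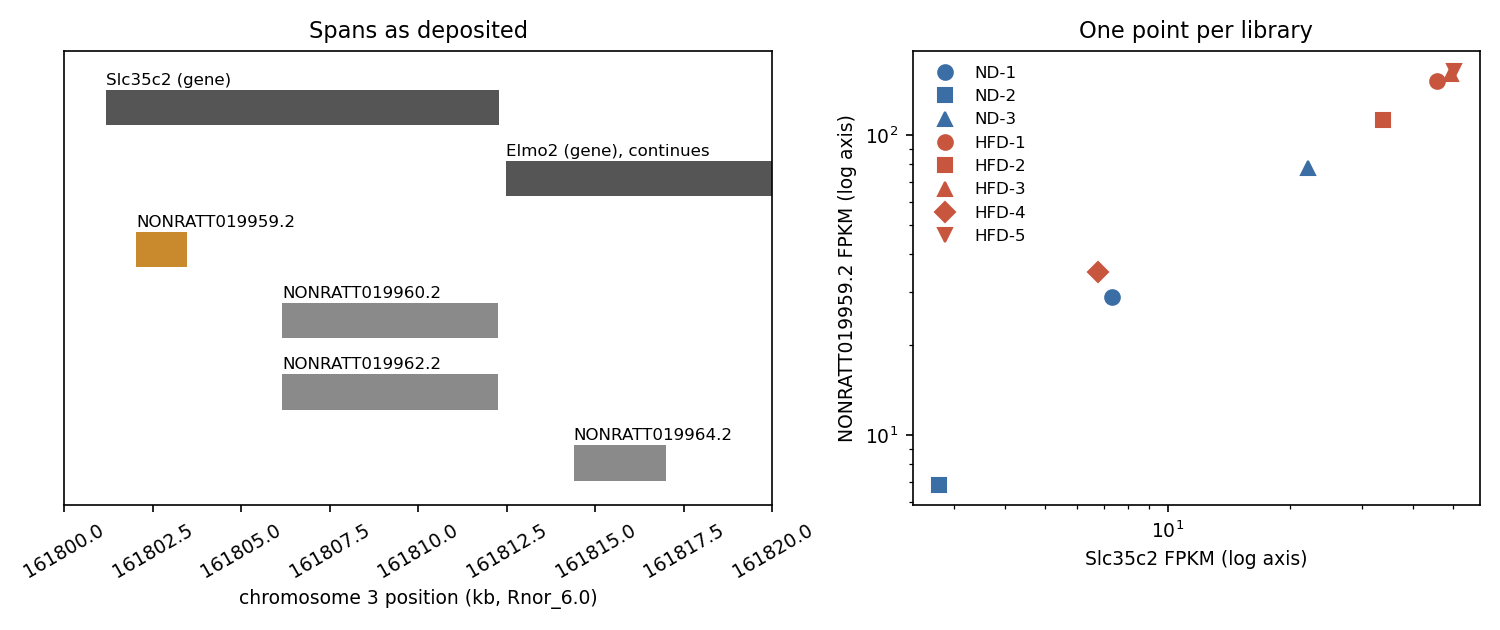
Left, spans of 2 genes and 4 lncRNAs on chromosome 3 (x axis, kb, Rnor_6.0) as the deposited tables give them. Right, FPKM of NONRATT019959.2 against FPKM of Slc35c2 (both log scales, 1 point per library, blue ND, red HFD): ND-2 is lowest at 6.83 FPKM and HFD-5 highest at 163 FPKM of the lncRNA.

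**Figure D4:**
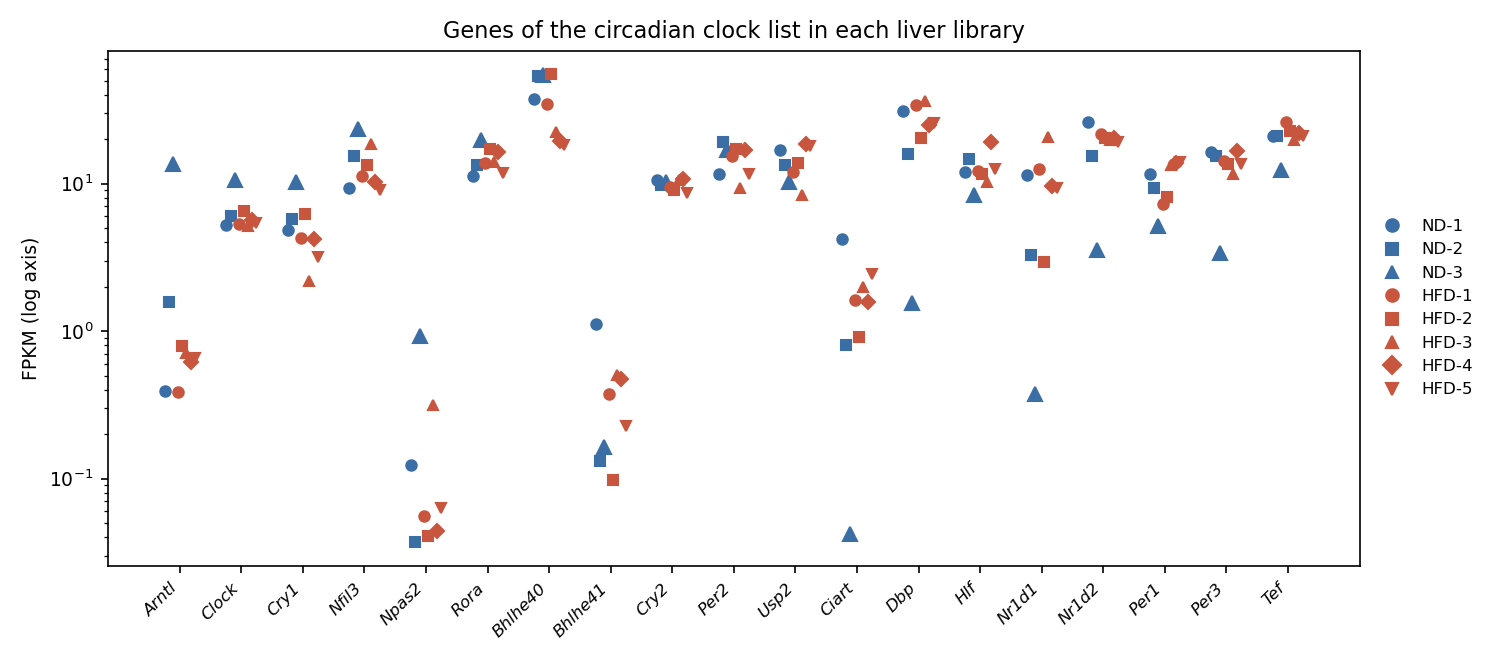
FPKM of 19 genes of the circadian clock list in each library (y axis, log scale; blue ND, red HFD). ND-3 (large blue triangles) lies above the other 7 libraries for the 6 genes at the left and below them for the 8 genes at the right.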

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

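All tests of explanations in this part were chosen after the results were seen. Of 137 sets of 5 HFD values looked at, 11 held a library far from the other 4 by Dixon's ratio of gap to range (critical value 0.71). Chance would give about 6.85 for independent, normally distributed values. The FPKM were not log transformed, and genes and lists vary together, so the count that chance gives here is not known. Tm7sf2 was at 26.1 FPKM in HFD-3 against 3.51 to 7.27 FPKM (ratio 0.834), Gadd45b at 13.3 FPKM in HFD-3 against 2.05 to 4.51 FPKM (0.782), Npas2 at 0.317 FPKM in HFD-3 against 0.0408 to 0.0636 FPKM (0.917), and the cell cycle score of HFD-3 at 0.951 against -0.171 to -0.0278 (0.872). In HFD-2, Phgdh was at 14.4 FPKM against 0.918 to 4.18 FPKM (0.757) and Cpb1 at 1.33 FPKM against 0.261 to 0.505 FPKM (0.771). In HFD-1 the xenobiotic score was at 0.337 against 0.0739 to 0.125 (0.806). In HFD-4, Hlf was at 19.2 FPKM against 10.2 to 12.5 FPKM (0.75), NONRATT019962.2 was at 34.5 FPKM against 204 to 273 FPKM (0.711) and TCONS_00183685 at 0.0778 FPKM against 0.0106 to 0.0222 FPKM (0.827). NONRATT012966.2 was at 1.52 FPKM in HFD-5 and at most 0.000179 FPKM in the other 4 (ratio 1).

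Clock genes of ND-3 differed from those of the other 7 libraries. Of 20 tested members of the clock list, 15 lay outside the range of the others, 7 higher, Arntl, Npas2, Clock, Cry1, Nfil3 and Rora among them, and 8 lower, namely Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per1, Per3 and Ciart, and the highest count for any other library was 7, in HFD-3. A first version of this test used 13 clock genes picked for their phase after most values of ND-3 had been seen (12 of 13, highest other library 4). It was replaced by the whole list, which had been fixed beforehand, after its result was known. The tables argue only weakly against a mislabelled HFD library: the cholesterol synthesis score of ND-3 lay 1.43 SDs of the HFD scores above the highest of them. That list was chosen after it had parted the diets with ND-3 counted as ND. The score of ND-1, 0.322, lay just above the highest HFD score, 0.242 in HFD-3. Over the 15 genes the other 3 deep libraries differed from the shallow ones by a median of -0.0169 of the log2 difference of ND-3 (quartiles -0.0896 and 0.166). For these genes this argues also against the deep library set. The limit is that they were picked for ND-3 lying outside the range of all others, deep libraries included, which favours a low value. A first version of that test, since dropped, used Arntl alone. A candidate explanation is another phase of the daily clock, for example from collection at another time of day, and the labels used here give no time. No biological explanation from the design was tested, because both other ND libraries lack the pattern.

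The 2 depth sets differed in 427 genes with the diet in the model, more than any of the other 34 splits of the libraries into 4 and 4 (highest 72). After every library was thinned to 12678616 counts, 123 genes still differed, against at most 41 in the other splits, so depth alone does not account for the sets. The count after thinning was 28.8% of that before, a value that met neither bound first set for this test, so the comparison with other splits was put in its place after that value was seen. The sets may be separate library or sequencing batches, for which the 427 genes stand against 72, and the labels name none. Both sets hold both diets, though ND-2 is the only ND library of the shallow set. The diet comparison with the set as a covariate is given in the report.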

How the results depend on the processing

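The depth-set covariate, limma on log2(FPKM + 1) and edgeR on rescaled lncRNA fragments were chosen after seeing the data, and all other alternatives before. The count of 1 gene went to 18 without a filter on low counts (more genes tested), 131 with DESeq2 (6286 adjusted p missing), 5 with the depth set, and 0 with FPKM of at least 5 and in all 7 limma fits on FPKM (655 to 826 genes at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 9 genes: 8 without ND-1, 9 without HFD-5, 2 without HFD-3 and 0 without ND-2, HFD-2 or HFD-4. Fer1l5 did not pass in 13 of 20 alternatives. The count of 2 lncRNAs went to 9 without a variance trend and to 0 to 3 without 1 library, 0 without ND-1 or ND-3. TCONS_00183685 could not be tested without any 1 ND library, since the filter drops it. The count of 9 lists went to 5 with an estimated correlation, 5 with fry, 13 with the replicate block, 7 with the depth set, pseudocount 0.1 or quantile normalization, and 8 to 12 without 1 library. The cause was not tested. Both synthesis lists, fatty acid oxidation and xenobiotic metabolism passed in every alternative of camera with the preset correlation and in fry. The amino acid list (0.339 with an estimated correlation, 0.34 with fry) and the bile acid list (0.138 and 0.188) did not pass with those tests. The cell cycle list had adjusted p of 0.924 (estimated correlation), 0.876 (fry), 0.199 (pseudocount 0.1), 0.17 (quantile) and 0.161 (depth set), and the sex-linked list 0.487, 0.34, 0.115, 0.167 and 0.185 in that order. Without 1 library the adjusted p ranged from 0.00113 to 0.122 (sex-linked), 6.26e-05 to 0.151 (bile acid), 0.000337 to 0.0847 (oxidative stress, highest without ND-2) and 0.00393 to 0.883 (cell cycle). Lists that turned direction were immediate early genes without ND-2 (0.00164 to 0.942), and acute phase (0.0311 to 0.962) and Kupffer cells (0.000474 to 0.934) without HFD-3. With an estimated correlation these did not pass there (adjusted p = 0.488, 0.463 and 0.447). Lists that newly passed without 1 library were erythroid cells (2.05e-12), immediate early genes (0.00265) and lymphocytes (0.0084) without ND-3, endothelial cells without ND-3 (0.0333), HFD-1 (0.0174) or ND-2, and oxidative phosphorylation without HFD-5 (0.0347). With an estimated correlation these did not pass, with adjusted p of 0.0548, 0.574 and 0.588 in the first 3 cases, 0.185, 0.195 and 0.251 for endothelial cells and 0.84 for oxidative phosphorylation. Values of other lists were on the same side of the threshold 318 times and newly passed 12 times. Directions of lists that did not pass were not compared.

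The replicate numbers showed no clear pairing of the samples: same-numbered libraries had correlations of 0.112, -0.275 and 0.0735. For ND-2 and ND-3 the same-numbered HFD library lies in the other depth set, so these values do not settle whether samples were paired. With the replicate block the counts were 0 genes (924 unadjusted), 0 lncRNAs (1034 unadjusted) and 0 lists with an estimated correlation, the sex-linked list was at 0.0682, and Lnc19959.2 had a log2 difference of 2.45, past an unadjusted threshold in limma. With the block the sign turned for Cdkn1a (-0.054), Hlf (-0.035), Usp2 (-0.28), Ppap2b (-0.086), Rora (0.023), Ciart (0.69), Apoa4 (-0.19) and NONRATT019964.2 (0.13). With the depth set it turned for Cdkn1a (-0.0015), Ppap2b (-0.038), Rora (0.021), Cpb1 (0.024), Cyp2c11 (0.0064) and Eif2s3y (0.0084). In limma fits on FPKM, Ciart was at 0.32 (pseudocount 1), 1.08 (0.1), 1.55 (0.01), 0.30 (quantile), 0.48 (equal sums), 0.32 (no trend) and 0.37 (weights). Rora was at 0.013, 0.015 and 0.015 with those pseudocounts and 0.013 without a trend, and LOC100909412 (ENSRNOG00000042543) at -0.0091 (equal sums) and -0.0096 (weights).

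Values that turned sign without 1 library ranged as follows. Without ND-1 they were Cpb1 (-0.88 to 0.13), Ciart (-0.63 to 2.25, also without HFD-2), Bhlhe41 (-1.14 to 1.05), Cyp2c11 (-0.19 to 0.072, also without HFD-3) and Hbb (-0.0095 to 0.92). Without ND-3 they were Hlf (-0.024 to 0.32), Usp2 (-0.12 to 0.29, also without HFD-4 or HFD-5), Ppap2b (-0.10 to 0.47), Nfil3 (-0.64 to 0.016), Per3 (-0.20 to 0.60), Rora (-0.18 to 0.24, also without HFD-5), Nr1d2 (-0.066 to 1.14) and Eif2s3y (-0.15 to 0.017). LOC100909412 (ENSRNOG00000042543; -0.084 to 0.14) turned without ND-2, HFD-1 or HFD-2, and NONRATT019964.2 (-0.17 to 0.028) without HFD-4 or HFD-5. Lnc19959.2 ranged from 1.20 to 2.90 (exact permutation p from 0.0286 to 0.19), under the threshold without ND-3 or HFD-4. Purb and Hnrnpa2b1 kept direction and did not pass in any alternative run. Of the other named genes and lncRNAs, 2101 values were on the same side of the threshold, 51 newly passed and 17 no longer passed. Agreement with a comparison of the authors was not run, because beside the values per library the tables used here hold group means and no fold change, p or call. On simulated counts with the real library sizes, the gene test found 96% of 4-fold and 52% of 2-fold changes, set only in genes above a set level. The lncRNA test found 50% of 4-fold changes, and both simulations left out the depth sets. Planting many changed genes makes the adjusted threshold easier to pass: 153 genes were called there and 1 in the real data. These shares therefore do not give the power of the real comparison.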

Other observations

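The test of shared signal over all lncRNAs and the counts over other arrangements were chosen before their results were seen, and the tests of Lnc19959.2 and of lncRNAs present in 1 diet after. The DESeq2 alternative placed 11 genes of fatty acid and triglyceride synthesis and 14 of cholesterol synthesis among its lower calls, and 5 of fatty acid oxidation and 6 of xenobiotic metabolism among its higher calls. Pnpla3, a lipid droplet protein, was at 8.07 to 151 FPKM in the ND libraries and 0.187 to 1.69 FPKM in the HFD libraries (log2 fold change -6.36, edgeR adjusted p = 0.0851), and without ND-2, the library at 151 FPKM, its log2 fold change was -4.15 (edgeR adjusted p = 0.117). Srebf1 and Scd1, a regulator of lipid synthesis and a desaturase, were at 118 ± 54.0 and 1469 ± 542 FPKM on chow and 66.0 ± 24.7 and 480 ± 425 FPKM on the high fat diet (adjusted p = 0.835 and 0.975). Bhmt, of methionine metabolism, was at 2412 ± 1505 and 824 ± 475 FPKM and Cps1, of the urea cycle, at 1753 ± 401 and 1155 ± 280 FPKM (adjusted p = 0.749 and 0.835).

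The number of lists that passed with an estimated correlation, 5, was reached by 1 of the 56 arrangements of the libraries, the real one, and the highest of the others was 1. This share is the smallest that 3 against 5 samples allow, and other counts were put through the same arrangements. Chance is thus argued against, but not excluded, for that count. More weight was given to it only after the other arrangements had been seen, and it fell to 0 without ND-2, to 1 without ND-3, HFD-1 or HFD-2 and to 4 without any other library, to 3 with the depth set and to 0 with the replicate block. Chance cannot be excluded for the count of 9 lists with the preset correlation, which 29 arrangements reached (highest other 14), for the 1 gene, which 9 arrangements reached (highest other 13), or for the 2 lncRNAs, which 19 reached (highest other 10). The arrangement with 13 genes, several times the real count, set ND-1, HFD-4 and HFD-5 against the rest. A structure of the samples other than diet is possible there, but was not tested. Both arrangements with 10 lncRNAs set 3 of the 4 shallow libraries against the rest. With the depth set as a covariate the diets differed in 5 genes and 3 lncRNAs. The 131 DESeq2 calls were not counted over other arrangements.

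Lnc19959.2 and Slc35c2 moved together: the ratio of their FPKM lay between 2.48 and 5.16 in the 8 libraries, and the SD of its log2 was 0.185 times that of Lnc19959.2 itself. A wider region that varies between animals is argued against by the next gene, Elmo2, whose log2 SD was 0.158 times that of Slc35c2. A candidate explanation is that a single signal was counted in both tables, and co-regulation of separate RNAs stays open, since the use of strand is not known. A diet effect on the lncRNA cannot be told apart from these, because 1 HFD library lies in the ND range and the ratio gave an exact permutation p of 0.554 between the diets. Over 11861 lncRNAs that overlap 1 expressed gene, the median correlation across libraries with that gene was 0.522, against 0.00828 with a random gene of similar level, a difference of 0.513 that is consistent with shared signal at many loci; genes are not independent replicates.

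Of the lncRNAs, 1 was under 0.5 FPKM in every library of a diet and at least 5 FPKM in every library of the other, TCONS_00183685, and 40 of the 56 arrangements gave as many (highest other 4), so chance cannot be excluded for such a pattern.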
